A study of Homo sapiens with 12 samples.

How the data were processed

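RNA from the prostate cancer cell lines 22Rv1 and LNCaP was measured on 12 two-colour Agilent whole human genome arrays. Per the labels, cells were grown in RPMI medium with serum and transfected with 20 uM SChLAP1 siRNA (siRNA-H or siRNA-J) or non-targeting siRNA, using Oligofectamine, at 12 h and 36 h after plating. Total RNA was taken with Trizol and an RNeasy kit. The SChLAP1 siRNA sample carried Cy5 and the control of its line Cy3 on every array, with no dye swap. The series text counts the 2 siRNAs as biological replicates of the treatment, 1 control sample, and 3 technical arrays per siRNA. Whether these share 1 RNA is not given in the sources used here. The arrays sit on 4 slides, each of which holds 1 line, with replicate 1 of both siRNAs on the first slide of a line and replicates 2 and 3 on the second.

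The authors deposited scanner files whose spot signals are intensity values, before any normalization, for Cy3 and Cy5 with the median of the local background. The deposited scanner files also give a log10 ratio of Cy5 over Cy3 after the dye normalization of Agilent Feature Extraction. The deposited series matrix holds the log2 ratio of Cy5 over Cy3, which equalled the scanner ratio times log2 of 10 on all 12 arrays (slope 3.32, correlation 1), so these sources give the same counts. Per the file headers Feature Extraction was version 9.5.1.1, whereas the labels name version 8.5.1.1, and the header version is taken as the one that made the files. Each array held 43376 spots of 41000 probes outside the controls. Median Cy3 signals ranged from 129 to 241 and median Cy5 signals from 154 to 240 between arrays, and 103 to 239 spots per array were marked as outliers by the scanner software. For arrays the number of arrays limits the precision.

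Ratios were computed in R 4.3.3 with limma (3.58.1), data.table (1.17.8) and statmod (1.5.0), and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized within each array by loess, with control spots given no weight. Outlier spots were left out and the spots of a probe averaged. A probe was kept when it was well above background in either channel on all 3 arrays of at least 1 group, which left 29922 probes, and 1 probe per gene name was used, that with the highest mean signal, which left 22021 genes. Of the 41000 probes 27745 received a symbol from the reference, 23958 by accession, 2755 by name and 1032 by synonym. Coordinates are those of the array in hg18.

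For knockdown against control the 3 arrays of each siRNA in a line were averaged, and limma fitted the 4 resulting columns with a mean per line, testing each line, the mean of both lines and LNCaP minus 22Rv1 against 0. This design has about 9 degrees of freedom per gene after moderation (8.99), and the spread is that between the 2 siRNAs of a line. The control is 1 sample per line, so its own spread is not in the test. The comparison of siRNA-H with siRNA-J used the 12 single arrays (13.4 degrees of freedom) and measures only the spread of these technical arrays. Genes were called at a Benjamini-Hochberg adjusted p of 0.05, two-sided.

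Named genes followed a rule fixed before the data were examined. For both lines these were the 12 largest changes each way among genes past the threshold with 1 sign on all 12 arrays. For each line they were the 6 largest each way with 1 sign on its 6 arrays, for the line difference the 5 largest each way without overlap of the arrays, and for siRNA-H against siRNA-J the 4 largest each way. SMARCA4, SMARCA2, SMARCB1 and the 4 members of each gene list with the smallest p in both lines were always included. A few genes that met this rule are not reported here. The 18 gene lists, also fixed before the data were examined, were androgen response, DNA replication, mitosis, MYC targets and ribosome biogenesis, p53 targets, interferon response, unfolded protein and ATF4 response, mesenchymal and invasion genes, epithelial genes, SWI/SNF subunits, hypoxia and glycolysis, cholesterol and fatty acid synthesis, NF-kB and cytokine genes, immediate early genes, neuroendocrine genes, stromal, endothelial and blood cell markers, genes near SChLAP1 on 2q31, and basal prostate genes. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Camera compares a list with all other genes, and fry tests whether its genes move, on balance, in 1 direction.

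The procedure was tested on simulated arrays with the spread of the real ones and 200 changed genes. The simulated groups varied independently, with no shared control sample and no dye bias of a probe. The counts of unchanged genes called below therefore do not cover false calls from those sources. For both lines it recovered 64% of genes changed 1.25-fold and 96% of those changed 1.5-fold, with 5 unchanged genes called. For a single line it recovered 2% and 66%, and 90% at 2-fold, with 3 unchanged genes called, and for the line difference 0% and 36%, and 82% at 2-fold, with 0 unchanged genes called. The comparison of the siRNAs recovered 60% at 1.25-fold with 7 unchanged genes called when siRNAs of a line had no spread of their own. When the simulated siRNAs had such a spread, as in the first form of this simulation, it called 3422 genes that no planted change had touched, since that comparison cannot tell such a spread from an effect of the siRNA.

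Alternatives were no background subtraction, median centring without loess, the scanner software's own ratios, the series matrix, 2 other filters, every probe or the mean of the probes, trended and robust moderation, the 12 arrays as independent or with blocks, each slide alone, and leaving out each array and each siRNA. Probes without a gene symbol were tested but not named, and SChLAP1, which has no named probe, was not analysed here.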

Results

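Gene expression was measured in the prostate cancer cell lines 22Rv1 and LNCaP after transfection with siRNA against SChLAP1, a long noncoding RNA of chromosome 2q31. Each line received either of 2 SChLAP1 siRNAs, called siRNA-H and siRNA-J, or a non-targeting control siRNA, at 12 h and again at 36 h after plating. The 12 two-colour arrays fall into 4 groups of 3, one group for each siRNA in each line. SChLAP1 siRNA was labelled with Cy5 and the control of the same line with Cy3 on every array, so each array gives the ratio of knockdown over control. Per array, 61.7% to 71.7% of the spots were well above background in Cy3 and 65.6% to 73.6% in Cy5. The number of arrays limits the precision, and the series text calls the 3 arrays of a group technical repeats. Replicates 2 and 3 sit on another slide than replicate 1, and whether all 3 come from the same RNA is not given in the sources used here.

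No probe of the array is named for SChLAP1. A single unnamed probe lies between its coding neighbours CWC22 and UBE2E3 in the hg18 coordinates of the array, and the level of SChLAP1 itself was not analysed here. All log2 ratios below are SChLAP1 siRNA over control, given with the standard error of the limma fit, and adjusted p-values are from limma over 22021 genes.

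The first question was which genes differed from control in the mean of both lines, a test that a gene changed mostly in 1 line can also pass. The most strongly higher gene was A2ML1, a protease inhibitor of the alpha-2-macroglobulin family, at a log2 ratio of 0.72 ± 0.0578 (1.65-fold, n = 4 siRNA means of 3 arrays each, limma adjusted p = 0.000673). KLF14, a Krüppel-like transcription factor, rose by 0.68 ± 0.0719, the hair keratin-associated gene KRTAP4-11 by 0.67 ± 0.0604. CSDC2, which encodes an RNA-binding cold shock domain protein, rose by 0.66 ± 0.0508. TOMM20L, related to a receptor of mitochondrial protein import, rose by 0.58 ± 0.058. The brightest probes for the small ribosomal subunit proteins RPS2 (0.61 ± 0.0418), RPS27 (0.58 ± 0.0427) and RPS28 (0.52 ± 0.0397) were higher as well. Rises were also seen for PLAAT5 (0.50 ± 0.0394), an acyltransferase gene, and SEC16B (0.49 ± 0.0599), which acts at exit sites of the endoplasmic reticulum.

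The deepest falls were those of TMED9, a cargo receptor between endoplasmic reticulum and Golgi, at −1.01 ± 0.0578 (limma adjusted p = 0.000319), and of the nuclear import receptor IPO7 at −0.94 ± 0.0425 (7.99e-05). Both were mostly 22Rv1 responses, as given below for the difference between the lines. PRPF19 and MAPT, named next, were so as well, with LNCaP values of −0.23 ± 0.0618 and −0.10 ± 0.0596 that did not pass and a line difference that did. For IPO7 and MAPT this rests on 1 probe, since their second probes gave line differences of −0.061 and −0.00061. Further falls were those of the AP-1 subunit FOS by −0.52 ± 0.0404, the growth arrest gene GADD45G by −0.48 ± 0.0449 and the circadian repressor PER1 by −0.45 ± 0.0588. The splicing factor PRPF19 (−0.52 ± 0.0437), the neuronal enolase ENO2 (−0.47 ± 0.0822), and the ribosome maturation factor TSR2 (−0.46 ± 0.044) fell as well. The xenobiotic-metabolising CYP1A1 (−0.46 ± 0.0626), the ephrin ligand EFNA3 (−0.44 ± 0.0452), the tau gene MAPT (−0.44 ± 0.0421) and the serine dehydratase SDS (−0.43 ± 0.04) completed the 12 named falls. The 22 genes named here had 1 sign on all 12 arrays, and their adjusted p-values were 0.00843 or below.

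In all, 3857 genes passed, 2253 higher and 1604 lower, and 2587 of them had 1 sign on all 12 arrays. Their median absolute log2 ratio was 0.196, 10 were at least 1.5-fold higher, 4 were at least 1.5-fold lower, and TMED9 was the only gene at least 2-fold lower. The line-wise lists shared 233 higher genes, against 22.6 for independent lists, and 121 lower genes, against 8.95, although both lines carried the same dye on the same side. Both line tests also use 1 shared spread per gene. A gene with a small spread passes more easily in both lines, which by itself raises the overlap above the counts for independent lists. Other probes of several named genes did not carry the same value. The 5 other RPS2 probes ranged from −0.36 to 0.17. The 3 brightest RPS2 probes, at mean log2 signals of 18.2, 17.9 and 15.4, gave 0.61, 0.17 and −0.36. The last of these passed lower in each line (limma adjusted p = 0.0134 in 22Rv1 and 0.0281 in LNCaP over all probes). The second RPS28 probe gave −0.061, at a mean log2 signal of 15.4 against 18.1 for the first, and the second PLAAT5 probe 0.022. The second SDS probe gave −0.076 and the second IPO7 probe −0.097. A second probe gave 0.28 for RPS27, −0.21 for MAPT and −0.19 for PER1. With the mean of a gene's probes RPS2 no longer passed. With the scanner software's own ratios, which called 1675 genes, or with median centring without loess, ENO2 no longer passed. Because no array swapped the dyes, a dye bias of a probe adds to these ratios, and the ratio leaves out the spread between control samples. Leaving out either siRNA of 22Rv1 left far fewer genes passing, and ENO2 lost its call without siRNA-J but not without siRNA-H.

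**Figure D1:**
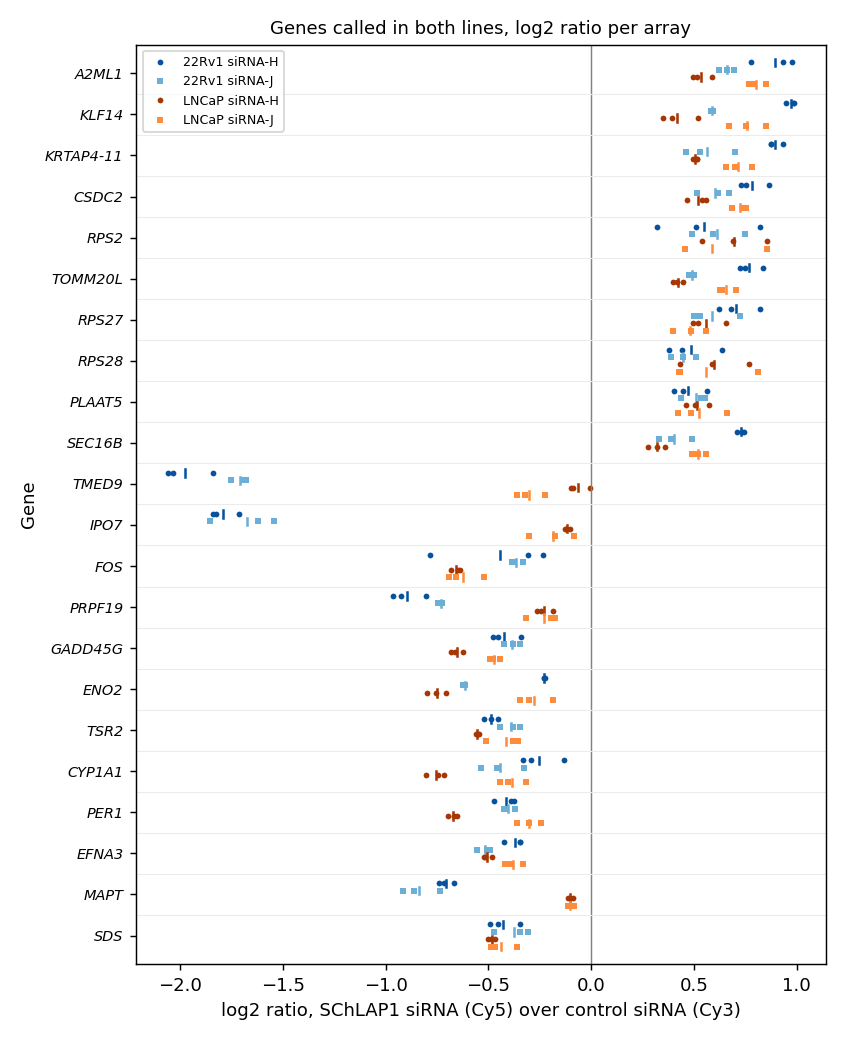
Log2 ratio of SChLAP1 siRNA over control (horizontal axis) for the 22 genes named for both lines (vertical axis), with 1 point per array, 1 colour per siRNA and line, and a short bar at the mean of the 3 arrays. All points of the upper 10 genes lie above 0 and all points of the lower 12 below 0, with TMED9 near −1.84 in 22Rv1 and near −0.18 in LNCaP.

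Among 18 gene lists fixed before the data were examined, 3 passed in both lines together by camera with the preset correlation. Of 29 hypoxia and glycolysis genes measured, 0 rose and 11 fell, and 15 fell when adjusted over the list alone. Their median log2 ratio was −0.16. It rested mostly on 1 siRNA per line, and on a different one in each. The medians were −0.0084 for siRNA-H and −0.28 for siRNA-J in 22Rv1, and −0.40 and −0.073 in LNCaP. The camera test against all other genes gave an adjusted p of 8.04e-06, but p = 0.934 with an estimated correlation and 0.567 with fry. The members included ENO2, the glycolytic enolase ENO1 (−0.33 ± 0.0599), ERO1A (−0.36 ± 0.0643), an oxidase of disulfide bond formation, and the hypoxia-induced NDRG1 (−0.32 ± 0.0517). Epithelial genes passed with 0 higher and 7 lower of 30 measured, 8 lower when adjusted over the list alone, and a median of −0.071. Examples were the tight junction claudins CLDN7 (−0.34 ± 0.0399) and CLDN4 (−0.30 ± 0.0404), the protease inhibitor SPINT1 (−0.33 ± 0.0422) and the epithelial transcription factor ELF3 (−0.37 ± 0.0552). The camera adjusted p was 0.000133, against p = 0.681 with an estimated correlation and 0.00616 with fry.

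In the unfolded protein and ATF4 response, 2 genes rose and 10 fell of 30 measured, with 3 rising and 11 falling when adjusted over the list alone, and a median of −0.065. The stress inhibitor of growth signalling DDIT4 (−0.27 ± 0.0454), the serine synthesis enzyme PHGDH (−0.24 ± 0.044), the disulfide isomerase PDIA6 (−0.21 ± 0.0402) and HERPUD1 (−0.21 ± 0.0429), a part of endoplasmic reticulum protein degradation, were examples. Camera gave an adjusted p of 0.0154 for this list, with p = 0.681 with an estimated correlation and 0.0151 with fry. All these lists kept their camera direction with the scanner software's ratios, which carry their own dye normalization, but turned when loess was left out. With median centring without loess the median of all genes was 0.13, and the list medians were 0.14 for hypoxia and glycolysis, 0.22 for epithelial genes and 0.24 for the unfolded protein list. Single genes turned with it, since NDRG1, ENO1, CLDN7, DDIT4, PHGDH, PDIA6 and HERPUD1 were then above 0, and ERO1A, SPINT1, CLDN4 and ELF3 did not pass. Of these CLDN7 (0.010), PHGDH (0.11) and PDIA6 (0.12) were above 0 but under the median of all genes.

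SWI/SNF subunits, a chromatin remodelling complex, did not move as a group, with 3 higher and 4 lower of 28 measured, the same counts when adjusted over the list alone, and camera adjusted p = 0.795. ARID1A rose by 0.34 ± 0.0425, its other probes giving 0.18 and −0.062, while SMARCB1 (−0.23 ± 0.041, limma adjusted p = 0.00843), BCL7C (−0.27 ± 0.0451) and SMARCD2 (−0.19 ± 0.0424) fell. SMARCD2 was at 0.10 with median centring without loess, below the median of all genes with that scaling (0.13). Of the genes said below to turn positive with it, KLK2, CDT1, MCM7, PLK3, ISG20, SREBF2 and BCL3 also stayed under that median. The ATPase genes SMARCA4 (0.027 ± 0.0486, limma adjusted p = 0.736) and SMARCA2 (0.097 ± 0.0525, 0.228) did not pass. The other SMARCA4 probes gave −0.15 and −0.20, and the last of these −0.27 in 22Rv1 (limma adjusted p = 0.0498 over all probes). Of 28 androgen response genes, 2 rose and 2 fell, in the same numbers when adjusted over the list alone (camera adjusted p = 0.489). ACSL3 rose by 0.38 ± 0.0427, though its second probe gave −0.034, and ZBTB10 rose by 0.17 ± 0.045. NDRG1 and the kallikrein KLK2 (−0.17 ± 0.0468) fell, KLK2 turning positive with median centring without loess.

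Of 30 mitosis genes 5 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 0.254). Among them were CCNB1 (0.30 ± 0.0452), the main mitotic cyclin, HMMR (0.17 ± 0.0393), DLGAP5 (0.16 ± 0.0398) and the proliferation marker MKI67 (0.15 ± 0.0398). Of 30 DNA replication genes 1 rose and 4 fell, again the same when adjusted over the list alone (0.201). In 22Rv1 this average joins opposite moves, with a list median of −0.23 for siRNA-H and 0.14 for siRNA-J. The licensing factor CDT1 fell by −0.31 ± 0.0442, the thymidine kinase TK1 by −0.25 ± 0.0568 and the helicase subunit MCM7 by −0.29 ± 0.067. All were positive with median centring without loess. With that scaling CDT1 (0.048) and MCM7 (0.126) lay below the median of all genes (0.133) and did not pass. The thymidylate synthase TYMS rose by 0.24 ± 0.0637. MYC targets and ribosome biogenesis genes gave 3 higher and 1 lower of 30, unchanged in number when adjusted over the list alone (0.808). In 22Rv1 the list medians were again opposite, −0.11 for siRNA-H and 0.080 for siRNA-J, as were those of cholesterol synthesis at −0.088 and 0.044. The MYC target values were UTP20 at 0.49 ± 0.045, WDR12 at 0.24 ± 0.0468, GNL3 at 0.18 ± 0.0397 and PES1 at −0.21 ± 0.0394. Of 29 p53 targets 2 rose and 3 fell, and 3 rose and 3 fell when adjusted over the list alone (0.808). Examples were TP53INP1 at 0.22 ± 0.0462, PHLDA3 at −0.37 ± 0.0414, PLK3 at −0.21 ± 0.04 and GADD45A at −0.19 ± 0.0457. PLK3 and GADD45A turned positive with median centring without loess.

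Interferon response genes gave 3 higher and 3 lower of 26, or 3 and 4 when adjusted over the list alone (camera adjusted p = 0.912). USP18 was at 0.16 ± 0.0416, though its second probe gave −0.059, and the antiviral MX1 at 0.16 ± 0.0438. IRF1 was at −0.20 ± 0.0411 and ISG20 at −0.32 ± 0.0489, the last turning positive with median centring without loess. Of 21 NF-kB and cytokine genes 0 rose and 2 fell, as when adjusted over the list alone (0.201). These were BCL3 (−0.23 ± 0.0541), which turned positive with that scaling, and the cytokine TNF (−0.19 ± 0.0458). NFKBIA (0.15 ± 0.0485) and NFKB2 (−0.12 ± 0.0396) did not pass. Immediate early genes gave 2 higher and 3 lower of 28, or 2 and 4 when adjusted over the list alone (0.499). Among them were FOS and the MAP kinase phosphatase DUSP6 (−0.22 ± 0.041) lower and EGR3 (0.16 ± 0.0399) and NR4A2 (0.14 ± 0.0402) higher. The control channel of EGR3 was below background in 22Rv1 and both its channels were in LNCaP, where its ratio carries no information. The control channel of NR4A2 was below background in LNCaP, and both genes turned negative with median centring without loess.

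Mesenchymal and invasion genes gave 2 higher and 3 lower of 19, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.808). Members were the transcription factor SNAI2 at 0.21 ± 0.0418, the integrin ITGA5 at −0.21 ± 0.0445 and the urokinase receptor PLAUR at −0.19 ± 0.0401. CDH2 passed at 0.15 ± 0.0406, but its control channel was below background in 22Rv1 and both its channels were in LNCaP, where its ratio carries no information. Its sign turned with median centring without loess. Cholesterol and fatty acid synthesis gave 2 higher and 3 lower of 30, or 3 and 3 when adjusted over the list alone (0.499). MVD was at −0.29 ± 0.0411. Lower as well were SREBF2 (−0.20 ± 0.0408) and PMVK (−0.15 ± 0.0395), which both turned positive with that scaling. Of 23 neuroendocrine genes 1 rose and 3 fell, the same when adjusted over the list alone (0.297). UCHL1 rose by 0.17 ± 0.0477, while ENO2, INSM1 (−0.22 ± 0.0397) and TUBB3 (−0.18 ± 0.0517) fell, TUBB3 turning positive with median centring without loess.

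Markers of stromal, endothelial and blood cells gave 3 higher and 0 lower of 17, or 5 and 0 when adjusted over the list alone (camera adjusted p = 0.201, fry adjusted p = 0.0165). They included the endothelial VWF (0.23 ± 0.0445) and the myeloid integrin ITGAM (0.24 ± 0.0571), while NKG7 (0.14 ± 0.0425) did not pass over all genes. Of 12 measured genes near SChLAP1 on 2q31, 3 rose and 0 fell, or 4 and 0 when adjusted over the list alone (0.201). They were NUP35 (0.39 ± 0.0633), a nuclear pore gene, NCKAP1 (0.20 ± 0.0399) and SESTD1 (0.20 ± 0.0504). DUSP19 (0.16 ± 0.0476) did not pass over all genes. Basal prostate genes gave 1 higher and 1 lower of 16, or 1 and 0 when adjusted over the list alone (0.201). DST was at 0.19 ± 0.0436, its other probes lying between −0.053 and 0.088, and TRIM29 at −0.14 ± 0.0412, against 0.11 for its second probe. EGFR (−0.26 ± 0.0923) and ITGB4 (−0.10 ± 0.0431) did not pass. The values of list members above are means of both lines, and for some 1 line carried most of the mean. In 22Rv1 and LNCaP these were −0.0037 and −0.37 for TNF, −0.092 and −0.37 for BCL3, −0.011 and −0.39 for IRF1, and −0.035 and −0.40 for INSM1. They were 0.41 and 0.025 for TP53INP1, −0.32 and −0.11 for DUSP6, 0.22 and 0.056 for NR4A2, and 0.080 and 0.27 for ZBTB10. The smaller value of each pair did not pass in its line, and the line difference passed for none of these 8 genes. No list call held with an estimated correlation in any comparison with the control. In both lines that correlation was negative for epithelial (−0.0263) and unfolded protein genes (−0.0249). Their unadjusted camera p still rose from 1.48e-05 to 0.0389 and from 0.00257 to 0.0757. The loss of these calls thus does not show that their genes were correlated. That setting cannot separate correlation from the few columns of the fit, 4 here against 12 arrays for siRNA-H against siRNA-J. List median and camera direction differed in sign for MYC targets, SWI/SNF subunits, mesenchymal, cholesterol and immediate early genes, whose medians all lay within 0.014 of 0. With the scanner software's ratios, of the list members named above only ACSL3, ARID1A, BCL7C, CCNB1, CDH2, CDT1, CLDN4, CLDN7, DDIT4, DUSP6, EGR3, FOS, INSM1, MVD, PES1, PHLDA3, PLK3, SMARCB1, SNAI2, SPINT1, SREBF2, UTP20 and VWF passed in the mean of both lines. A single array decided the calls of KLK2, MX1, CDH2, EGR3, NR4A2, UCHL1, TUBB3, SESTD1 and TRIM29.

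**Figure D2:**
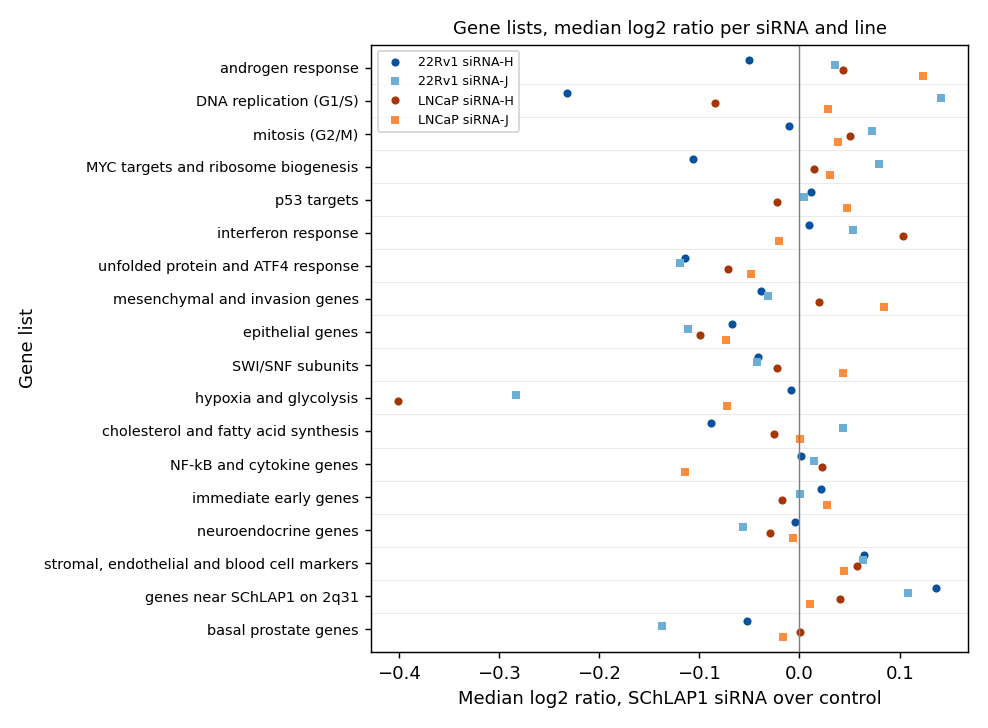
Median log2 ratio of SChLAP1 siRNA over control (horizontal axis) over the measured genes of each of the 18 lists (vertical axis), with 1 point for each siRNA in each line. The hypoxia and glycolysis medians were −0.28 for siRNA-J and −0.0084 for siRNA-H in 22Rv1, against −0.40 for siRNA-H and −0.073 for siRNA-J in LNCaP. With median centring without loess the median over both siRNAs was positive in each line, 0.13 in 22Rv1 and 0.21 in LNCaP.

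For 22Rv1 alone, the falls were deeper than in LNCaP for a handful of genes. TMED9 fell by −1.84 ± 0.0817 (n = 2 siRNA means of 3 arrays each, limma adjusted p = 3.47e-05) and IPO7 by −1.73 ± 0.06 (7.79e-06). MED18, a subunit of the Mediator complex, fell to a Cy5 signal above background on only 1 of 6 arrays, so that the size of its fall is not exact. HNRNPA0, an RNA-binding protein gene, fell by −1.14 ± 0.0752. The RNA polymerase regulator RPRD1B fell by −1.01 ± 0.0763, and TNRC6B, a partner of Argonaute in RNA silencing, by −0.93 ± 0.0695. CD86, a costimulatory ligand for T cells, rose by 0.83 ± 0.076. It was followed by KLF14 (0.78 ± 0.102), A2ML1 (0.78 ± 0.0817), KRTAP4-11 (0.73 ± 0.0854), the prothymosin gene PTMA (0.72 ± 0.062) and CSDC2 (0.69 ± 0.0718). All 12 had 1 sign on all 6 arrays of the line, and the adjusted p of each was 0.00775 or below.

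In 22Rv1, 1644 genes passed, 892 higher and 752 lower, of which 6 were at least 2-fold lower and none 2-fold higher. Genes near SChLAP1 on 2q31 gave 2 higher and 0 lower of 12, or 4 and 0 when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.0177, but p = 0.56 with an estimated correlation). Among them were NUP35 (0.41 ± 0.0896) and NCKAP1 (0.27 ± 0.0565). The hypoxia (camera adjusted p = 0.00875, p = 0.926 with an estimated correlation), epithelial (0.0101, p = 0.56) and unfolded protein (0.0141, p = 0.56) lists had medians of −0.14, −0.085 and −0.079. These became 0.13, 0.16 and 0.18 with median centring without loess. Those lists held 1, 3 and 5 genes lower with 0, 0 and 1 higher, or 1, 6 and 10 lower with 0, 0 and 3 higher when adjusted over the list alone. The hypoxia median of 22Rv1 came from siRNA-J (−0.28), as that of siRNA-H was −0.0084.

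Other 22Rv1 probes gave −0.066 for IPO7, −0.46 for HNRNPA0, −0.056 for RPRD1B, −0.068, 0.057 and 0.19 for TNRC6B and at most 0.30 for PTMA. Those of IPO7 and RPRD1B were dim, at mean log2 signals of 7.45 and 6.55. With the mean of their probes TNRC6B and PTMA no longer passed. With siRNA-J alone the test called 4 genes, namely TMED9, IPO7, HNRNPA0 and 1 probe without a symbol. With siRNA-H alone it called 5 genes, namely TMED9, IPO7, HNRNPA0, RPRD1B and PRPF19. The scanner software's ratios called 120 genes and kept CD86, TMED9, IPO7, HNRNPA0, RPRD1B and TNRC6B among the 12 named. Without siRNA-H or without siRNA-J in LNCaP, each of which changes the shared estimate of the spread, 3783 genes passed in 22Rv1.

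In LNCaP, the strongest rise was that of STRIP2, which encodes a striatin-interacting protein, at 0.97 ± 0.0762 (n = 2 siRNA means of 3 arrays each, limma adjusted p = 0.00472). MED18 was at least 1.55-fold higher and the calcium-binding S100A6 at least 1.52-fold higher, since their control channel was below background on all 6 arrays. The fitted log2 ratios were 0.68 ± 0.121 and 0.64 ± 0.0797. A2ML1 rose by 0.67 ± 0.0817, RPS2 by 0.64 ± 0.0591 and the apolipoprotein gene APOL6 by 0.63 ± 0.0811, its control channel being above background on 1 of 6 arrays. The small nucleolar RNA gene SNORD14E fell by −0.79 ± 0.0749 and the inducible heat shock gene HSPA6 by −0.69 ± 0.14. FOS fell by −0.64 ± 0.0572, CYP1A1 by −0.57 ± 0.0885, GADD45G by −0.56 ± 0.0635 and CD86 by −0.52 ± 0.076. The adjusted p-values of the 12 genes were 0.0365 or below, with 1 sign on all 6 arrays of the line.

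In LNCaP, 820 genes passed, 558 higher and 262 lower. None of their fitted ratios reached 2-fold, although only lower bounds could be given for MED18 and S100A6. Hypoxia and glycolysis genes gave 0 higher and 2 lower of 29, or 12 lower when adjusted over the list alone, with a median of −0.22 (camera adjusted p = 4.57e-07, but p = 0.997 with an estimated correlation). They included ENO2 (−0.52 ± 0.116) and ERO1A (−0.47 ± 0.091). The hypoxia median of LNCaP was −0.40 with siRNA-H and −0.073 with siRNA-J. Epithelial genes gave 0 higher and 5 lower of 30, also when adjusted over the list alone, with a median of −0.073 (3.03e-05, p = 0.613 with an estimated correlation), including ELF3 (−0.46 ± 0.078) and CLDN4 (−0.39 ± 0.0571). Both medians were positive with median centring without loess, at 0.21 and 0.22.

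The second STRIP2 probe gave −0.011 in LNCaP and the second SNORD14E probe 0.33. SNORD14E was represented by that probe and positive when probes had to be above background on all 12 arrays. Without siRNA-H in 22Rv1 or without siRNA-J in 22Rv1, each of which changes the shared estimate of the spread, 141 genes passed and MED18 and HSPA6 did not. Without siRNA-J in LNCaP 1664 passed, and without LNCaP siRNA-H replicate 3 500 passed. The scanner software's ratios called 197 genes in LNCaP, with STRIP2, S100A6, APOL6 and FOS kept of the 12 named. MED18 and HSPA6 did not pass with no background subtraction or with trended robust moderation, RPS2 and SNORD14E with the mean of their probes, and MED18 and CD86 with the first slide alone. HSPA6 also did not pass without LNCaP siRNA-H replicate 1 (adjusted p = 0.0558) or without LNCaP siRNA-J replicate 3 (0.0501).

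Whether the lines responded differently was tested as LNCaP minus 22Rv1, a contrast in which a dye bias common to all arrays cancels. A deviation of the 1 control sample of a line, or of its slides, does not cancel and is not in the spread. MED18 was lower than control in 22Rv1 and higher in LNCaP, with a fitted difference of 2.29 ± 0.171 log2 units (limma adjusted p = 0.00193). The size of this difference is not exact, since the control channel was below background on all 6 arrays in LNCaP and Cy5 was above it on only 1 of 6 in 22Rv1. TMED9 (1.66 ± 0.116) and IPO7 (1.58 ± 0.0849) fell in 22Rv1, while their LNCaP values of −0.18 ± 0.0817 and −0.15 ± 0.06 did not pass. STRIP2 differed by 1.22 ± 0.108, and BPNT1, a nucleotidase of sulfate metabolism, by 1.12 ± 0.0875. BPNT1 fell in 22Rv1 by −0.66 ± 0.0618 and rose in LNCaP by 0.46 ± 0.0618. In the other direction CD86 differed by −1.35 ± 0.108, SNORD14E by −0.90 ± 0.106 and the endoplasmic reticulum protein gene CKAP4 by −0.61 ± 0.0789. MAGED4B differed by −0.52 ± 0.0852 and SINHCAF, a member of a histone deacetylase complex, by −0.52 ± 0.0828.

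The difference passed for 216 genes, 195 of them higher and 21 lower in LNCaP relative to 22Rv1. With median centring without loess this balance was 405 higher and 380 lower. BPNT1 is among 7 genes for which every one of their 2 or more probes passed in 1 direction, a count chosen after the data were seen. ATG10 (0.66), an autophagy gene, and CASP8 (0.55), the initiator caspase, are others of these and were singled out after their values were seen. Genes near SChLAP1 had a median difference of −0.11 (camera adjusted p = 0.0479, p = 0.871 with an estimated correlation), with 0 of 12 passing on their own, also when adjusted over the list alone. In 22Rv1 both channels of APOL6 were below background and the control channels of SNORD14E and MAGED4B were, so that the sizes of these differences are not exact. The scanner software's ratios called 0 genes in limma, against 2367 at an unadjusted p below 0.05, with a lowest adjusted p of 0.0637. Without siRNA-H in 22Rv1 10 genes passed, without siRNA-J in 22Rv1 6, without siRNA-H in LNCaP 330 and without siRNA-J in LNCaP 616. Of the 10 named genes SNORD14E, CKAP4, MAGED4B and SINHCAF did not pass without siRNA-H in 22Rv1, and these 4, STRIP2, BPNT1 and CD86 did not pass without siRNA-J in 22Rv1. SINHCAF and SNORD14E did not pass with the mean of their probes, nor did SNORD14E and MAGED4B with median centring without loess. MAGED4B did not pass without 22Rv1 siRNA-J replicate 3 (−0.48) or without LNCaP siRNA-J replicate 2 (−0.50). MAGED4B did not pass with no background subtraction either, nor MAGED4B and SINHCAF with the first slide alone. Second probes gave differences of 0.028 for STRIP2, −0.061 for IPO7 and 0.067 for SNORD14E, and the other SINHCAF probes −0.082 and −0.41.

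**Figure D3:**
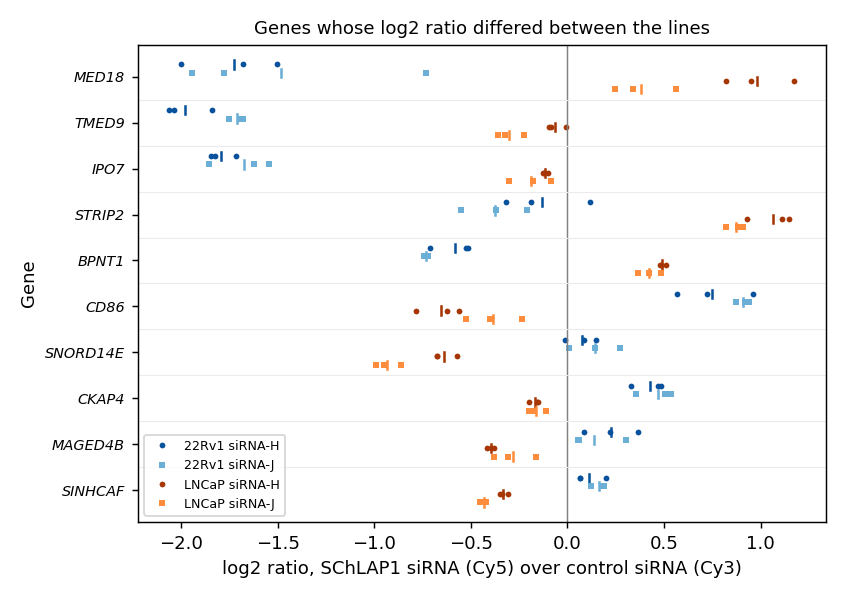
Log2 ratio of SChLAP1 siRNA over control (horizontal axis) for the 10 genes named for the difference between the lines (vertical axis), with 1 point per array, 1 colour per siRNA and line, and a short bar at the mean of the 3 arrays. The 6 LNCaP arrays and the 6 22Rv1 arrays do not overlap for any of the 10 genes, which the rule for naming them required. The MED18 gap rests on a control channel below background in LNCaP.

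How far the 2 siRNAs differed was tested as siRNA-H minus siRNA-J on single arrays, so that these p-values hold only the spread of arrays called technical repeats. In 22Rv1 the stathmin gene STMN4 was higher with siRNA-H by 0.74 ± 0.0545 (n = 3 arrays per siRNA, limma adjusted p = 1.91e-05), as were the glycosyltransferase gene GGTA1 (0.69 ± 0.054), IQCN (0.68 ± 0.0546) and the growth factor PTN (0.64 ± 0.0501). The heterochromatin protein gene CBX5 was lower with siRNA-H by −0.87 ± 0.0459, the Wnt antagonist DKK1 by −0.78 ± 0.087, the replication helicase subunit MCM3 by −0.65 ± 0.0602 and the thioesterase gene ACOT7 by −0.64 ± 0.0518. In LNCaP the phosphatase regulator PPP1R10 was higher with siRNA-H by 1.56 ± 0.053, DIDO1 by 1.39 ± 0.0609 and RBBP6 by 1.08 ± 0.0478. POTEE (−0.81 ± 0.0663), the dehydrogenase gene DHRS2 (−0.80 ± 0.0493), the arrestin-domain gene ARRDC4 (−0.76 ± 0.0732) and TBRG1 (−0.76 ± 0.0534) were lower with siRNA-H.

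In 22Rv1 2941 genes passed, 1597 higher and 1344 lower with siRNA-H, and in LNCaP 4421, 2389 higher and 2032 lower. IQCN was higher with siRNA-H in both lines, whereas DHRS2 was higher with siRNA-H in 22Rv1 (0.59 ± 0.0493) and lower in LNCaP, a pattern its second probe shared at 0.67 and −0.87. Further LNCaP probes gave between −0.34 and 0.34 for DIDO1, −0.018 and 0.014 for RBBP6, −0.22 and 0.12 for TBRG1, and −0.081 and −0.40 for POTEE. Without 22Rv1 siRNA-J replicate 2 the 22Rv1 count was 1726 and without 22Rv1 siRNA-J replicate 3 it was 1580. The second slide of each line alone gave 1304 in 22Rv1 and 2558 in LNCaP, and median centring without loess gave 569, of which 39.4% were higher with siRNA-H, and 2170, of which 66.7% were higher. PTN did not pass with the scanner software's ratios.

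**Figure D4:**
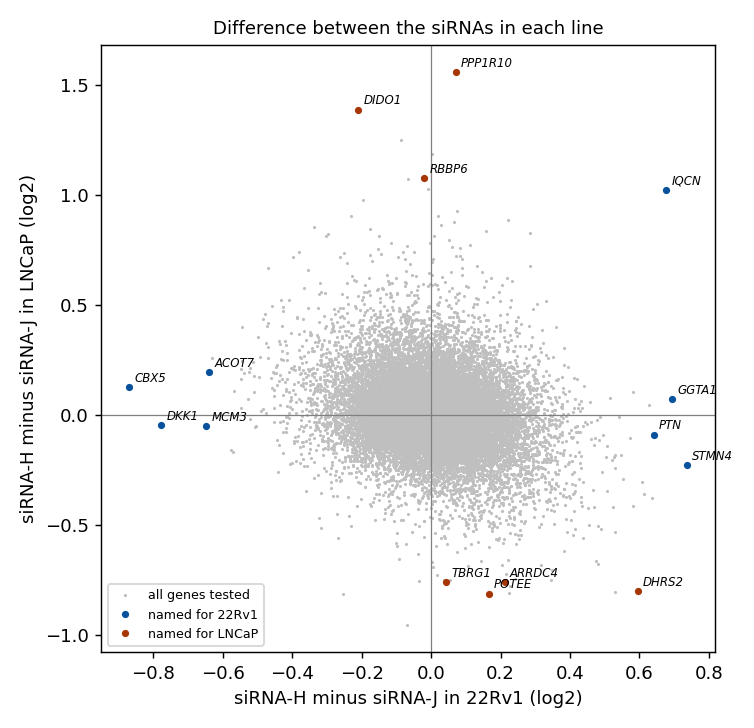
SiRNA-H minus siRNA-J in log2 units in 22Rv1 (horizontal axis) and in LNCaP (vertical axis), with 1 grey point per gene tested and the genes named for each line in colour. PPP1R10 lies highest, at 1.56 in LNCaP and 0.070 in 22Rv1, and DHRS2 lies at 0.59 in 22Rv1 and −0.80 in LNCaP.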

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

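The tests of a single slide, of the brightest probe in the line difference, of same-oligo effects, of array position and of crossed siRNA names were chosen only after the result was seen. The crossed-names test also replaced an earlier form after the gene list results for siRNA-H against siRNA-J were seen. The dye, transcript and split tests were set before their own values, although counts of genes whose probes all pass had been seen before the dye and transcript tests.

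The first pattern is that 233 higher and 121 lower genes were shared by the lines, numbers that the spread shared by both line tests may raise. Such sharing would follow from a change of the transcripts and also from a dye bias of single probes. Likeness of the siRNAs within a line was not taken as evidence for either, since they share a control sample whose spread was not measured. A simulation assumed that this control varies as much as the siRNAs do. That assumption itself fixed the correlation, at 0.495 in 22Rv1 and 0.498 in LNCaP, against 0.624 and 0.422 observed. The second probe was read for genes called in the mean of both lines with a log2 ratio of at least 0.4 in either direction. Such calls can include genes changed mostly in 1 line, such as IPO7, and not only the shared genes. The second probe had the called sign for 75% of 36 genes (95% interval 57.8 to 87.9). A change of the transcript itself required the interval to lie above an even split, which it did, in a test that could have failed. Agreement in sign alone does not show that the transcript changed. That share was −1.67 percentage points from the share among genes of the line difference, where a constant dye bias cancels (76.7% of 60 genes, Fisher's exact test p = 1). The sets can share genes, since IPO7 and MAPT have a second probe and passed both tests at that size, whereas Fisher's exact test takes them as separate. With 36 and 60 genes a dye effect stays open although the value met the bound set for its absence, and the second probes carried a median of only 0.17 of the first probe's log2 ratio. Second probes have a lower signal than the first, which may itself reduce their ratios.

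The second pattern is the set of genes whose response differed between the lines. A single slide is not its source: over the called genes the median ratio of the first-slide to the second-slide difference was 0.989. Whether it rests on the brightest probe alone stays open, because second probes carried a median of 0.185 of the first probe's difference (bootstrap interval 0.0675 to 0.269, 60 genes), which spans the bound set for it. Probe-specific signals could therefore account for part of the genes, while BPNT1, whose second probe gave 0.79, is a gene for which the probes go together. The lower signal of second probes may also have reduced the median of 0.185. A biological difference between the lines, such as their genotypes, was not tested, nor was a deviation of the single control sample of a line.

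The third pattern is that siRNA-H minus siRNA-J went opposite ways in the lines. Across genes, which are not independent replicates, the correlation between the lines was −0.214 (rank correlation −0.186). Of 1107 genes called in both lines 897 went opposite ways and 210 the same, against 293 and 297 for independent calls. Array position would give a positive correlation in replicates 2 and 3, which gave −0.169, and effects of each oligo on the same genes would give a positive one only if the siRNA names are right in both lines, so that oligo effects stay open. Crossed siRNA names in 1 line may be the source and stay open too, since of the gene lists that passed in both lines 1 went opposite ways (hypoxia and glycolysis) and 1 the same way (DNA replication); differences between single transfections were not tested.

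For the counts themselves, 3 against 3 arrays allow 10 splits, too few for a share under 0.05: the real split gave 2941 genes in 22Rv1 against 0 for the highest other, and 4421 in LNCaP against 1, each real split being 1 of 10.

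The genes below stood out because the test of the difference between the lines passed. LNCaP minus 22Rv1 was 2.29 for MED18, 1.66 for TMED9, 1.58 for IPO7, 1.22 for STRIP2 and 1.12 for BPNT1. It was 1.1 for HNRNPA0, 0.96 for RPRD1B, 0.82 for S100A6, 0.79 for TNRC6B, 0.69 for APOL6, 0.67 for MAPT and 0.59 for PRPF19. It was −1.35 for CD86, −0.90 for SNORD14E, −0.61 for CKAP4, −0.52 for MAGED4B and −0.52 for SINHCAF. The median of the list of genes near SChLAP1 was −0.11, a call lost with an estimated correlation (camera adjusted p = 0.871), with 0 of its 12 genes passing. The second probe of HNRNPA0 gave a difference of 0.20, that of RPRD1B 0.10 and that of MAPT −0.00061. The other TNRC6B probes gave 0.048, 0.085 and −0.17, and the other SINHCAF probes −0.082 and −0.41.

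Signal was also present in control features that no comparison used. In all, 10 spike-in probes were above the negative controls on all 12 arrays, with mean log2 ratios from −3.01 to 2.96 and standard deviations over the arrays from 0.0412 to 0.0868.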

How the results depend on the processing

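The count of genes whose probes all pass was added after the data were seen, and all other alternatives were set before. Counts are given as both lines, 22Rv1, LNCaP and line difference, against 3857, 1644, 820 and 216, and the cause was not tested. Median centring without loess gave 14975, 9390, 14408 and 785, and 569 and 2170 for siRNA-H against siRNA-J in 22Rv1 and LNCaP, with 74.9%, 80.6%, 76.1% and 51.6% of calls higher. The scanner software's ratios and the series matrix gave 1675, 120, 197 and 0. No background subtraction gave 541 in LNCaP and 136 for the difference, and trended robust moderation 411 in LNCaP. The 12 technical arrays taken as replicates gave, as independent 10513, 8592, 7441 and 2021, with siRNA by line as a random block 6425, 4270, 3259 and 582 (correlation 0.389), with slide 12878, 11311, 10163 and 4141 (−0.13), and with replicate number 12203, 9162, 8048 and 1779 (−0.0905). The numbers did not pair arrays, as same-numbered siRNA-H and siRNA-J arrays correlated at −0.0625 to 0.231 across genes, and the fixed replicate block gave 2665 and 4227 for siRNA-H against siRNA-J. The first slide alone gave 2105, 588, 313 and 108, and the second slide 1304 and 2558 for siRNA-H against siRNA-J. Requiring all probes of a gene gave 241, 86, 20 and 7, out of 5896 genes with 2 or more probes. For those 5896 genes the brightest probe gave 1145, 496, 238 and 64. Leaving out an array or siRNA gave 504 to 4440, 4 to 3783, 141 to 1664 and 6 to 616, and 1580 to 3070 and 3008 to 5191 for siRNA-H against siRNA-J. A lone siRNA was assumed to vary like those of the other line. Among single arrays, LNCaP fell to 500 without LNCaP siRNA-H replicate 3, and 22Rv1 siRNA-H against siRNA-J to 1726 and 1580 without 22Rv1 siRNA-J replicate 2 and 3. The other filters, every probe, the mean of probes and the slide as a fixed block left each count within 1.5 times.

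Of the values of single genes, 3887 kept their side of the threshold, 380 lost and 50 gained a call, and of list values 171 kept, 14 lost and 19 gained. A change of sign was not counted where a value passed in neither fit. With median centring without loess, which gave medians over all genes of 0.13, 0.10 and 0.18 in both lines, 22Rv1 and LNCaP but moved single genes further or the other way, these values in both lines took the other sign: NDRG1 0.14, KLK2 0.098, CDT1 0.048, TK1 0.25, MCM7 0.13, PLK3 0.049, GADD45A 0.16, ISG20 0.068, DDIT4 0.24, PHGDH 0.11, PDIA6 0.12, HERPUD1 0.25, CDH2 −0.14, CLDN7 0.010, SMARCD2 0.10, ENO1 0.18, SREBF2 0.060, PMVK 0.17, BCL3 0.13, EGR3 −0.13, NR4A2 −0.055 and TUBB3 0.20. Those of these values that were positive but at 0.13 or below did not exceed the median of all genes. List medians took the other sign too. They were 0.24, 0.18 and 0.31 for unfolded protein in both lines, 22Rv1 and LNCaP. They were 0.22, 0.16 and 0.22 for epithelial and 0.14, 0.13 and 0.21 for hypoxia genes, and 0.27 for cholesterol in LNCaP. The median was positive with either scaling for cholesterol in both lines (0.0031 with loess, 0.23 without) and p53 targets in LNCaP (0.021 and 0.29). With probes above background on all 12 arrays another SNORD14E probe was used, giving 0.33 in LNCaP and 0.067 for the difference. Without 1 array these lost their call in both lines: without 22Rv1 siRNA-H replicate 1 TRIM29 (−0.14), replicate 2 TUBB3 (−0.15), replicate 3 CDH2 (0.13), NR4A2 (0.12) and TRIM29 (−0.13). Without 22Rv1 siRNA-J replicate 1 they were TRIM29 (−0.13), replicate 2 CDH2 (0.14), EGR3 (0.13), NR4A2 (0.12), TUBB3 (−0.17) and TRIM29 (−0.13), replicate 3 CDH2 (0.14) and UCHL1 (0.16). Without LNCaP siRNA-H replicate 1 these were NR4A2 (0.12), TUBB3 (−0.19) and SESTD1 (0.15), replicate 2 CDH2 (0.13) and TRIM29 (−0.14), replicate 3 UCHL1 (0.16), TUBB3 (−0.19) and TRIM29 (−0.13). Without LNCaP siRNA-J replicate 1 they were EGR3 (0.13) and UCHL1 (0.16), replicate 2 KLK2 (−0.16), NR4A2 (0.13), TUBB3 (−0.18) and TRIM29 (−0.14), replicate 3 MX1 (0.16) and TUBB3 (−0.17). DUSP19 gained a call without 22Rv1 siRNA-H replicate 1 (0.16) or 2 (0.16), 22Rv1 siRNA-J replicate 1 (0.18), LNCaP siRNA-H replicate 2 (0.17) or LNCaP siRNA-J replicate 1 (0.16). NKG7 gained one without 22Rv1 siRNA-H replicate 2 (0.14), 22Rv1 siRNA-J replicate 3 (0.15), LNCaP siRNA-H replicate 2 (0.16) or LNCaP siRNA-J replicate 2 (0.15). In LNCaP HSPA6 lost its call without LNCaP siRNA-H replicate 1 (−0.68) or siRNA-J replicate 3 (−0.74), and the MAGED4B difference lost its call without 22Rv1 siRNA-J replicate 3 (−0.48) or LNCaP siRNA-J replicate 2 (−0.50). The control channel of MED18, S100A6, APOL6, SNORD14E, MAGED4B, PTN, CDH2, EGR3 and NR4A2 was below background on all arrays of at least 1 line, which limits their ratios, and both channels were for APOL6 in 22Rv1 and for CDH2 and EGR3 in LNCaP.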

Other observations

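The gene list tests of siRNA-H against siRNA-J, and the sets of histone and ribosomal protein genes, were tests chosen after the data were seen. Their p-values are adjusted over these 20 lists and hold technical spread only. In 22Rv1, DNA replication genes were lower with siRNA-H than with siRNA-J. Of them 23 of 30 passed lower and 0 higher, with a median of −0.35 (camera adjusted p = 7.92e-05 with an estimated correlation). They were led by the helicase subunit MCM3 (−0.65 ± 0.0602) and the initiation factor MCM10 (−0.57 ± 0.0475). MYC targets (11 lower and 1 higher of 30, p = 0.00216 with an estimated correlation), cholesterol synthesis (9 and 0 of 30, p = 0.00271) and mitosis genes (10 and 0 of 30, p = 0.0117) were lower as well. Immediate early genes were higher (6 higher and 1 lower of 28, limma camera adjusted p = 0.0389 with an estimated correlation). In LNCaP, 10 of 30 DNA replication genes were lower with siRNA-H and 0 higher (median −0.10, p = 0.023 with an estimated correlation). Among them was the ribonucleotide reductase subunit RRM2 (−0.49 ± 0.045). Targets of p53 were lower (5 and 0 of 29, limma camera adjusted p = 0.0475 with an estimated correlation). NF-kB and cytokine genes were higher (10 higher and 1 lower of 21, median 0.16, p = 0.0258 with an estimated correlation), led by the apoptosis inhibitor BIRC3 (0.71 ± 0.0634). The medians of these lists kept their sign with no background subtraction, with median centring without loess and with the scanner software's ratios.

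Hypoxia and glycolysis genes went opposite ways in the lines. In 22Rv1 19 of 29 were higher with siRNA-H and 0 lower (median 0.20, p = 0.000116 with an estimated correlation). The chemokine receptor CXCR4 was at 0.61 ± 0.0431 and ANKRD37 at 0.48 ± 0.0488. In LNCaP 25 of 29 were lower and 2 higher (median −0.37, p = 0.000119 with an estimated correlation). ANKRD37 was at −0.68 ± 0.0488 and the lactate dehydrogenase LDHA at −0.57 ± 0.048. The vascular peptide ADM (0.24 ± 0.0473) and the oxygen sensor EGLN3 (0.28 ± 0.0749) were higher. Histone genes in LNCaP were lower with siRNA-H for 38 of 65 and higher for 5 (median −0.25, p = 0.00221 with an estimated correlation), H2BC21 at −0.55 ± 0.0628 among them. In 22Rv1 15 were higher and 5 lower (median 0.056, limma camera adjusted p = 0.145 with an estimated correlation). These signs held with all 4 scalings. No other fixed list passed with an estimated correlation in either line.

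Against control in both lines, 37 of 80 ribosomal protein genes passed higher and 2 lower, with a median of 0.13 (unadjusted camera p = 2.55e-10, p = 0.291 with an estimated correlation). The median stayed positive under all 4 scalings, but the counts did not hold. With the scanner software's ratios 10 passed higher in both lines and 0 in each single line, against 22 and 23, and with median centring without loess 78 passed higher. The medians were 0.038 (limma camera p = 0.11 with the preset correlation) with the scanner software's ratios and 0.71 with median centring without loess. In LNCaP 7 of the 80 were higher and 0 lower with siRNA-H than with siRNA-J (median 0.067, p = 0.0265 with an estimated correlation). The 5 other RPS2 probes ranged from −0.36, which passed lower in each line over all probes, to 0.17, and the second RPS28 probe gave −0.061.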
